A study of Mus musculus with 6 samples.

How the data were processed

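RNA was extracted from frozen liver with TRIzol and RNeasy columns, and stranded libraries were made after mRNA capture, per the labels' protocols. The submitters' processing notes name FastQC, STAR 2.6.0c, DESeq2 and the mouse build mm10. The read counter, its strand setting and the gene annotation are not given in the sources used here. Each of the 6 mice gave 1 library and 1 column of the deposited table, and replicates were numbered in accession order, which pairs no mice. The titles carry a different animal number for each library.

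The deposited signal is a normalised count per gene for 24501 genes. Within each column every value was a whole multiple of that column's smallest step, within 0.1 of a whole number for 100% of values, so the values were gene counts divided by 1 factor per library. Dividing by the step gave the whole reads, which summed to 33389673, 35113627 and 37390345 in Control replicates 1, 2 and 3 and to 33547532, 33274223 and 36649147 in Gata4LKO replicates 1, 2 and 3. No pair of libraries agreed within counting noise: the chi-square per degree of freedom was 31.4 or more for each of the 15 pairs. Alb took the most reads, 4.24% to 8.4% of a library. The authors' table of their own comparison holds a log2 fold change, its standard error and p-values per gene, under the column names of DESeq2. A copy of the authors' adjusted p-values inside the count table differed from that table for 391 genes, 385 of them without a symbol, and was not used.

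The main test was fixed before the data were examined: limma on log2(value + 1) with an intensity trend, 14385 genes with a mean of at least 10, a two-sided moderated test with no covariate, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. For the targeted and the fixed lipoprotein genes an exact two-sided permutation test was added, whose smallest p is 0.1. The 38 gene lists, also fixed beforehand, were tested with camera (preset correlation of 0.01) where at least 5 members were measured, which left 33. Camera with an estimated correlation and fry were run beside it. Members were named by rule: Gata4, the 12 largest changes in each direction with a mean of at least 50, non-overlapping groups and an official symbol, up to 4 members of smallest p per described list, and Apoa1, Apob, Abca1, Scarb1 and Lcat. Lists were described by members where camera or a member passed, and the GATA list in any case. Some members that this rule would name are not given here. R 4.3.3 ran limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

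The alternatives tried were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, equal library sums, quantile normalisation, TMM factors, limma without the trend or with robust variance, library weights, edgeR and DESeq2 on the recovered reads, and leaving out each library. A non-hepatocyte marker score as a covariate was chosen after seeing the data. Coordinates are from GENCODE M21, built on the same assembly, in which 24480 of the gene identifiers were found.

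The tests were tried on simulated counts with the means, library sizes and dispersions of the 14385 genes of this comparison. Of 100 genes changed 2-fold, limma recovered 60, edgeR 60 and DESeq2 70, and of 100 changed 4-fold they recovered 94, 94 and 95. False calls were 19, 18 and 40, which is 11%, 10.5% and 19.5% of the calls, above the nominal 5%. These shares come from a single simulation of independent genes, with 100 changed at each fold. They need not carry over to the calls of the real comparison. With no gene changed, limma called 1 gene, edgeR 1 and DESeq2 27. A simulated list of 20 genes with 10 raised passed camera (adjusted p = 1.14e-11) but not camera with an estimated correlation (adjusted p = 0.0843), and 0 of 32 unchanged lists passed. The simulated genes were independent of each other, so the lists of this simulation do not show how camera's preset correlation behaves where genes move together.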

Results

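Liver RNA was sequenced from 6 male C57BL/6J mice in 2 groups of 3. All carried floxed alleles of Gata4, which encodes a zinc finger transcription factor. Controls received an empty adeno-associated virus of serotype 8 (AAV8). Mice of the group labelled Gata4LKO received AAV8 carrying Cre recombinase under Tbg, a promoter active in hepatocytes. Injection was at 8 weeks of age, and the animals were 11 weeks old, had eaten a Western diet for 3 weeks and had fasted for 6 hours at collection, per the labels. A further label places collection 7 days after injection, and the series text mentions refed animals, which the sample labels do not. The libraries held 33274223 to 37390345 reads. The question was which liver genes differ when Cre is delivered to hepatocytes with floxed Gata4.

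The targeted gene was examined first. Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692, minus strand, mm10) had normalised read counts of 704, 637 and 546 in the controls and 867, 848 and 895 in the libraries labelled Gata4LKO. The group means were 629 ± 78.9 and 870.0 ± 23.3 (SD, n = 3 each). The log2 fold change was 0.47 with a standard error of 0.10, and it missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0641). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. Counts of this gene therefore did not show a loss in the libraries labelled Gata4LKO, and every direction below rests on the labels alone. A count over the whole gene cannot separate deleted from retained exons, the labels do not name the floxed exons, and liver cells that the promoter does not target can also carry Gata4 transcripts. DESeq2 on the recovered reads gave an adjusted p of 0.00712 for the same gene, and over all alternatives it ranged from 0.00712 to 0.478 at log2 fold changes from 0.33 to 0.56. Among the 4 measured relatives and cofactors of the GATA family, Zfpm1, the cofactor FOG1, fell by 0.84 on the log2 scale (SE 0.13, limma adjusted p = 0.0285). The log2 fold changes of Zfpm2, Gata2 and Gata6 were 1.30, 0.38 and 0.03, none passed, and that of Gata6 was negative with quantile normalisation. Adjusted over the list alone, 1 of the 4 was lower and 0 were higher.

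**Figure D1:**
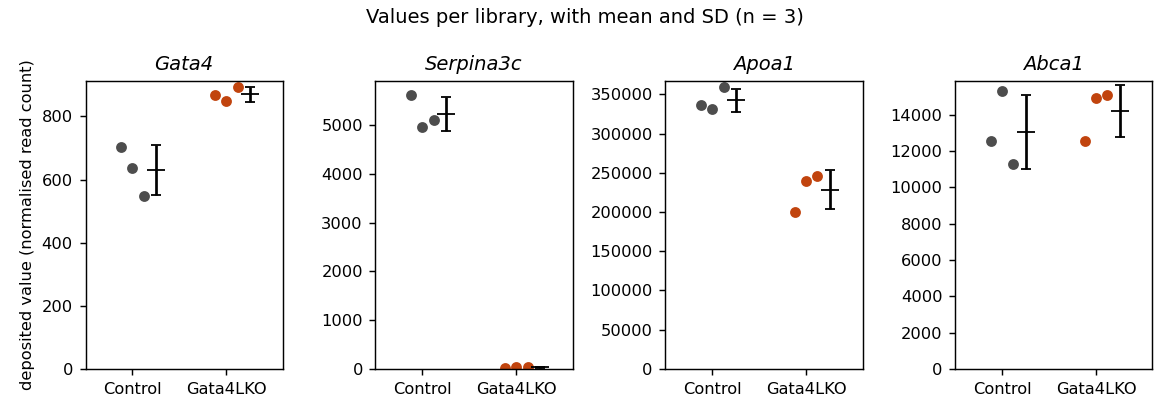
Normalised read counts of Gata4, Serpina3c, Apoa1 and Abca1 per library (points) on linear axes from 0, with the mean and SD of each group (black, n = 3). Serpina3c lay between 4965 and 5621 in the controls and between 22.5 and 34.1 in the libraries labelled Gata4LKO, and Gata4 lay above all control values in the latter.

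Serpina3c, a serine protease inhibitor of the alpha-1-antichymotrypsin family, fell by 7.44 on the log2 scale in the libraries labelled Gata4LKO, while Cfd, which encodes complement factor D (adipsin), rose 46.0-fold. The zinc importer Slc39a4 and the desmosomal cadherin Dsg1c also fell. Over all 14385 genes tested, 296 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 162 higher and 134 lower. At least 2-fold changes were seen for 119 of them, 68 higher and 51 lower. Values of the groups did not overlap for 4073 genes, 28.3% of those tested, where chance gives 10% on average, and all 296 changed genes were among them. Where genes move together a single split can lie far from that average, and the share in other splits was not counted. Of the 296 genes, 273 were also called by edgeR on the recovered reads and all 296 by DESeq2, which called 1370. The count of 296 leaned on each library: it was 143, 792 and 56 without Control replicates 1, 2 and 3, and 143, 140 and 27 without Gata4LKO replicates 1, 2 and 3. The 2-fold count of 119 was 39 without Control replicate 3, 478 without Control replicate 2, 77 without Gata4LKO replicate 2 and 24 without Gata4LKO replicate 3. Scaling all libraries to equal sums gave 458 genes, of which 71.6% were higher, against 54.7% with the deposited scaling. With a score of non-hepatocyte markers as a covariate, chosen after seeing the data, 6 genes passed, 5 of them among the 296.

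Serpina3c (ENSMUSG00000066361, chromosome 12, 104146382 to 104153870, minus strand) went from 5229 ± 346 to 29.6 ± 6.21 normalised reads (SD, n = 3), so that it fell by 7.44 on the log2 scale (SE 0.16, limma adjusted p = 2.1e-06). Lrit1, Dsg1c and Rnd2 fell with log2 fold changes of -3.28, -3.23 and -2.61. Aldh1b1, a mitochondrial aldehyde dehydrogenase, fell by 2.24, from 2360 ± 849 to 477 ± 83.5. A pair of zinc importers, Slc39a4 and Slc39a2, fell with log2 fold changes of -2.15 (SE 0.16) and -1.93 (SE 0.23). The receptor tyrosine kinase Erbb4 and the peptidase Trhde fell with log2 fold changes of -2.06 and -2.14. Idi1-ps2, Cyp2g1 and Clec2h fell with log2 fold changes of -2.36, -2.34 and -1.73. Idi1-ps2 is a processed pseudogene, and the last pair belong to gene families, so their reads may be split among near-identical copies. The same holds for Serpina3c, Ugt2b37 and Cyp4a31.

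Cfd (chromosome 10, 79890853 to 79892655, plus strand) rose 46.0-fold, with a log2 fold change of 5.52 and a standard error of 0.59 (limma adjusted p = 0.0118). Its normalised counts were 20.6, 52.0 and 21.5 in the controls and 3207, 1199 and 648.0 in the libraries labelled Gata4LKO. Without Gata4LKO replicate 1 its log2 fold change was 4.90. It did not pass without the variance trend (adjusted p = 0.0558) or with the marker score as a covariate, at 4.38 (0.127), and its adjusted p ranged from 7.4e-11 to 0.127 over all alternatives. Cfd belongs to the adipose tissue list, and at most 3 reads of Adipoq and 5 of Plin1 were present in any library. Trarg1 had 0, 2 and 4 reads in the controls and 11, 10 and 7 in the libraries labelled Gata4LKO, too few to be tested. The other adipose markers with enough reads to be tested, Fabp4 and Car3, had log2 fold changes of 0.62 and -0.40 without passing. Ugt2b37, a glucuronosyltransferase, rose 8.27-fold and the axon guidance gene Sema5b 5.22-fold. The p53 targets Eda2r and Phlda3 rose 5.06-fold and 4.57-fold. The fatty acid hydroxylase gene Cyp4a31 and the 5'-nucleotidase gene Nt5e rose 4.56-fold and 4.30-fold, and the export pump Abcc4 rose 4.29-fold. Vnn1, a pantetheinase, rose 3.92-fold and Serpina7, the thyroxine-binding globulin gene, 3.87-fold. The noncoding RNA Pvt1 rose 3.35-fold and Lrfn3 rose 3.34-fold. Of the 64 changed genes named by the rule, Cfd, Eda2r, Serpina3c, Dsg1c and Slc39a4 stayed called whichever library was left out. The other 59 lost the call without at least 1 library: 34, 3 and 50 of the 64 were lost without Control replicates 1, 2 and 3, and 35, 28 and 58 without Gata4LKO replicates 1, 2 and 3. With the marker score as a covariate, Serpina3c and Dsg1c alone of the 64 stayed called, so Eda2r and Phlda3 lost their calls there.

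**Figure D2:**
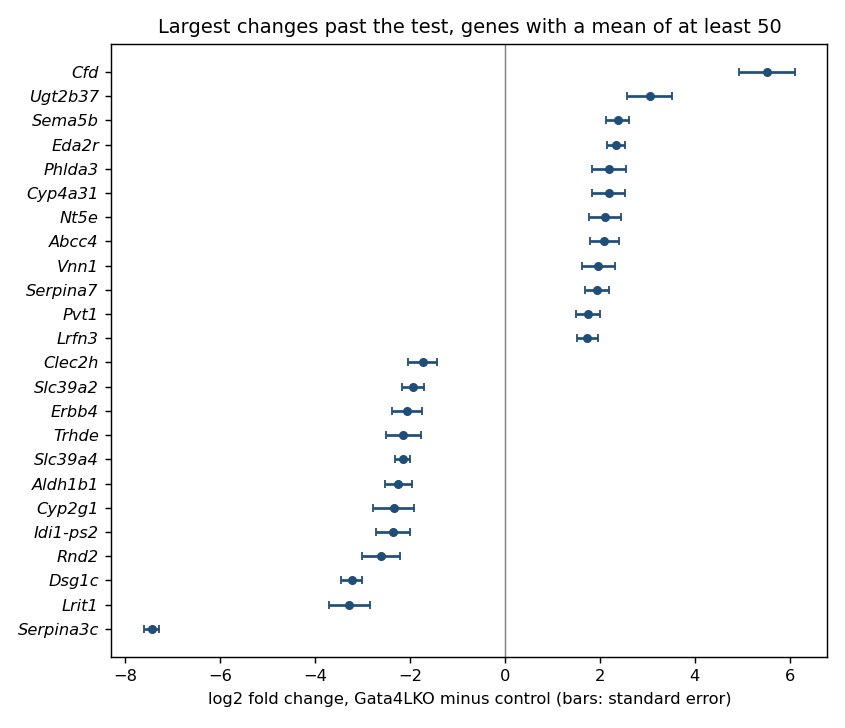
Log2 fold changes (points) and standard errors (bars) of the 12 largest rises and the 12 largest falls among genes past the test with a mean of at least 50 normalised reads, non-overlapping groups and an official symbol, from 3 libraries per group. Serpina3c at -7.44 and Cfd at 5.52 lie apart from the other 22 genes drawn, which range from -3.28 to 3.05.

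Among lipoprotein genes, the triglyceride lipase Lpl rose 2.42-fold (limma adjusted p = 0.027) and the endothelial lipase Lipg 2.66-fold (0.0293), while the hepatic lipase Lipc fell by 0.48 on the log2 scale (0.0312). These were the 3 of 28 measured members past the test, and adjusted over the list alone 4 were higher and 7 lower. Apoa1, the main protein of high-density lipoprotein, had 342659 ± 14536 normalised reads in the controls and 228320 ± 24964 in the libraries labelled Gata4LKO (SD, n = 3). Its log2 fold change of -0.59 with a standard error of 0.18 missed the threshold (limma adjusted p = 0.115, exact permutation p = 0.1), and DESeq2 on the recovered reads called it with an adjusted p of 1.01e-05. Over all alternatives its adjusted p ranged from 1.01e-05 to 0.586 and its log2 fold change from -0.65 to -0.47. Apob, the cholesterol exporter Abca1, the receptor Scarb1 and the acyltransferase Lcat had log2 fold changes of 0.24, 0.13, 0.08 and 0.02, with standard errors of 0.19, 0.13, 0.11 and 0.08. None of these passed (limma adjusted p from 0.491 to 0.901), and their exact permutation p-values were 0.2, 0.6, 0.8 and 1. With the marker score as a covariate Abca1, Scarb1 and Lcat had negative values. The lipoprotein list as a whole did not pass camera, a test of a list against all other genes (Benjamini-Hochberg adjusted p = 0.375). Its mean log2 fold change was 0.02 and its median -0.04, and the test pointed down.

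Targets of the fatty acid sensor PPARA and genes of fatty acid oxidation rose as a list. Of 27 measured members, 8 rose and 0 fell over all genes, and 21 rose adjusted over the list alone. The list's median log2 fold change was 0.48 (camera adjusted p = 8.4e-11, adjusted p = 0.423 with an estimated correlation). The peroxisomal enzyme genes Ehhadh and Acaa1b rose by 0.99 and 1.09 on the log2 scale (SE 0.13 and 0.17), the acyl-CoA synthetase Acsl1 by 1.05 (SE 0.14) and the mitochondrial Hadhb by 0.47 (SE 0.08). Lipid droplet genes also rose as a list, with 4 of 20 members higher, 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.582 with an estimated correlation). Plin4 and Plin2, which coat lipid droplets, rose 3.19-fold and 2.01-fold. Fitm2, needed for droplet formation, rose by 0.85 and G0s2, an inhibitor of adipose triglyceride lipase, by 1.29 on the log2 scale.

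Cholesterol synthesis genes fell as a list (camera adjusted p = 0.0026, adjusted p = 0.706 with an estimated correlation), with a median log2 fold change of -0.36 over 24 members. Relative to the control mean this list stood at -0.0010, -0.25 and 0.26 in Control replicates 1, 2 and 3 and at -0.08, -0.49 and -0.41 in Gata4LKO replicates 1, 2 and 3, so the groups overlapped. Only Stard4, a sterol carrier, passed alone, with a log2 fold change of -0.72 (SE 0.10), and adjusted over the list alone 4 were lower and 1 higher. With the marker score as a covariate the cholesterol list did not pass (mean -0.04, camera adjusted p = 0.721; 3.51e-05 to 0.721 over the alternatives with the preset correlation), and without Control replicate 3 its mean was -0.20. Hsd17b7 had a log2 fold change of 0.62 with a limma adjusted p of 0.0586. Of 20 targets of the sterol receptor LXR, Lpl rose and Abcg5, a sterol exporter subunit, fell by 0.86 (SE 0.16, limma adjusted p = 0.0444). Abcg5 missed the threshold by edgeR on the recovered reads (adjusted p = 0.0508). Its partner Abcg8 had a log2 fold change of -0.74 (limma adjusted p = 0.0533). Adjusted over the list alone, 4 LXR targets were higher and 4 lower, and the list did not pass (camera adjusted p = 0.766). Its mean was 0.02, its median was -0.06 and the test pointed down. Fatty acid and triglyceride synthesis did not pass either (camera adjusted p = 0.234), with 0 of 21 members past the test over all genes and 1 higher and 5 lower adjusted over the list alone. Without Gata4LKO replicate 1 that list was lower, with a mean log2 fold change of -0.49 (camera adjusted p = 0.00103; 0.00103 to 0.727 over the alternatives with the preset correlation). In the bile acid list, Baat, which conjugates bile acids, fell by 0.66 and the export pumps Abcc4 and Abcc3 rose by 2.10 and 0.59, while Abcb4 had 0.43 without passing. The list's camera adjusted p was 0.375, and adjusted over the list alone 7 members were higher and 1 lower.

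Several lists of hepatocyte genes fell, in the same libraries in which markers of other liver cells rose. Hepatocyte transcription factors and secreted proteins had a median log2 fold change of -0.18 over 25 members (camera adjusted p = 0.0026, adjusted p = 0.423 with an estimated correlation). The call was lost with quantile normalisation, at a mean of -0.15 (camera adjusted p = 0.125; 0.000369 to 0.125 over the alternatives with the preset correlation). No member passed alone: Cebpa, Foxa1, Foxa2 and Ttr had log2 fold changes of -0.42, 0.52, -0.94 and -0.49 (limma adjusted p from 0.0721 to 0.0996), and adjusted over the list alone 4 were lower and 1 higher. Markers of periportal hepatocytes fell as a list (camera adjusted p = 0.00014, adjusted p = 0.423 with an estimated correlation), with 20 of 21 fold changes negative. Aldh1b1 and Gls2, a liver glutaminase, passed alone, and 5 were lower adjusted over the list alone. With edgeR on the recovered reads Aldh1b1 passed (adjusted p = 0.0159) and Gls2 did not (0.0508). Hsd17b6 and Hsd17b13 had log2 fold changes of -1.73 and -0.31 with limma adjusted p of 0.0604 and 0.0642. The hepatocyte and periportal lists both kept their calls with the marker score as a covariate. Their means there were -0.26 and -0.43 (camera adjusted p = 0.0077 and 0.0102, and 0.708 for each with an estimated correlation). Pericentral markers did not pass (camera adjusted p = 0.341). Of these 22, Slc13a3 rose by 0.91 and Tbx3 by 0.72 while Cyp2c29 fell with a log2 fold change of -1.30, Cyp1a2 had -0.80 without passing, and adjusted over the list alone 3 were higher and 2 lower.

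Urea cycle and amino acid genes fell as a list (camera adjusted p = 0.00068, adjusted p = 0.703 with an estimated correlation), with 3 of 25 members lower both over all genes and adjusted over the list alone. By edgeR on the recovered reads 1 of the 25 was lower, and Gls2 missed the threshold (adjusted p = 0.0508). Otc, which makes citrulline in the urea cycle, Gls2 and Gldc fell with log2 fold changes of -0.87, -0.80 and -0.45 (SE 0.09, 0.15 and 0.08), and Hal had -0.52 without passing. Relative to the control mean the urea cycle list stood at -0.32, 0.04 and 0.27 in Control replicates 1, 2 and 3 and at -0.30, -0.45 and -0.18 in Gata4LKO replicates 1, 2 and 3, so the groups overlapped. Its mean of -0.31 was -0.47 without Control replicate 1 and -0.17 without Control replicate 3, and with the marker score as a covariate it did not pass (camera adjusted p = 0.199; 1.19e-07 to 0.199 over the alternatives with the preset correlation). Xenobiotic metabolism fell as a list (camera adjusted p = 0.022, adjusted p = 0.423 with an estimated correlation). Of its 27 members 3 fell and 1 rose, and 8 were lower and 3 higher adjusted over the list alone. The carboxylesterase Ces2a and the cytochromes Cyp2c29 and Cyp2c55 fell with log2 fold changes of -0.86, -1.30 and -4.19, while Abcc3 rose. Reads of the Cyp2c family can be shared among its copies. Cyp2c55 also lay under a mean of 50 normalised reads, so its fold change depends more on the pseudocount. With a filter of a mean of at least 50 the xenobiotic list stood at a mean of -0.25, against -0.38, and lost its call (camera adjusted p = 0.0734). Complement and coagulation genes fell weakly (camera adjusted p = 0.022, adjusted p = 0.706 with an estimated correlation), with a median of -0.14 over 31 members. Mbl2 alone passed, with a log2 fold change of -0.65, and was also the 1 member past the test adjusted over the list alone, while F10, Masp1 and Proc had -0.34, -0.35 and -0.24. Circadian clock genes fell as a list (camera adjusted p = 0.023, adjusted p = 0.582 with an estimated correlation). Dbp fell by 0.79, and Per3, Clock and Nr1d2 had -0.74, 0.35 and -0.32 without passing. Adjusted over the list alone, 5 clock genes were lower and 1 higher. The complement list lost its call without Control replicate 2 (camera adjusted p = 0.156) and without Gata4LKO replicate 1 (0.317, at a mean of -0.04). The clock list lost its call without Control replicate 2 (0.163) and Gata4LKO replicate 2 (0.0544), and the xenobiotic list without Gata4LKO replicate 2 (0.0634). All 3 lists also lost it with quantile normalisation (complement 0.186, clock 0.0933 and xenobiotic 0.106), and the complement list overlapped between the groups, Control replicate 3 standing at -0.05 and Gata4LKO replicate 2 at -0.02. Over the alternatives with the preset correlation the adjusted p ranged from 0.00521 to 0.317 for the complement list, from 0.00306 to 0.163 for the clock list and from 0.00081 to 0.127 for the xenobiotic list.

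Targets of p53, the transcription factor activated by DNA damage, rose as a list. Of 18 members, 5 rose and 0 fell over all genes, 12 rose adjusted over the list alone, and the median log2 fold change was 0.64 (camera adjusted p = 2.4e-08, adjusted p = 0.423 with an estimated correlation). Besides Eda2r and Phlda3, the cyclin Ccng1 rose by 0.72 (SE 0.07, limma adjusted p = 0.0101) and the kinase Plk2 by 0.53 (SE 0.09, 0.0408). Cre, which recombines DNA, was given only to the group labelled Gata4LKO. Proliferation genes did not pass (camera adjusted p = 0.506), with 0 of 22 past the test over all genes or over the list alone.

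Markers of liver cells other than hepatocytes rose as lists. Sinusoidal endothelial markers had a median log2 fold change of 0.63 (camera adjusted p = 8.4e-11, adjusted p = 0.423 with an estimated correlation). Of 21 members 8 rose, 18 adjusted over the list alone, among them Dnase1l3, Pecam1, Cdh5 and Ehd3 at 0.69, 0.68, 0.96 and 0.91 on the log2 scale. Macrophage and Kupffer cell markers had a median of 1.21 (camera adjusted p = 2.9e-08, adjusted p = 0.582 with an estimated correlation). No macrophage gene passed over all genes, whereas 17 of 21 were higher adjusted over the list alone and all 21 fold changes were positive. C1qc, Clec4f, Csf1r and C1qa had log2 fold changes of 1.26, 1.18, 1.45 and 1.27 (limma adjusted p from 0.0757 to 0.0805). Stellate cell markers had a median of 1.15 (camera adjusted p = 1.5e-07, adjusted p = 0.585 with an estimated correlation), with 0 of 18 past the test over all genes and 17 adjusted over the list alone. Rgs5, Hgf, Reln and Colec10 had log2 fold changes of 1.5, 1.52, 1.29 and 1.31. Lymphocyte markers had a median of 0.88 over 14 members (camera adjusted p = 0.0042, adjusted p = 0.684 with an estimated correlation), with 0 past the test over all genes and 1 over the list alone. Cd3e, Ptprc, Cd8a and Cd4 had 1.30, 1.44, 2.30 and 0.59, and Ptprc was negative with the marker score as a covariate. In Control replicates 1, 2 and 3 Cd8a had 17.5, 1.04 and 0.93 normalised reads and Ptprc had 172, 297 and 64.5. The fold of Cd8a therefore depends on Control replicate 1 and on the pseudocount, and that of Ptprc on Control replicate 3. The lymphocyte call was lost without Control replicate 3, at a mean of 0.38 (camera adjusted p = 0.0773). With the marker score as a covariate, which is built from the macrophage, stellate and lymphocyte lists themselves, these lists had means of 0.28, 0.19 and -0.46 and did not pass (camera adjusted p of 0.0775, 0.156 and 0.156). The lymphocyte adjusted p ranged from 0.00012 to 0.156 over the alternatives with the preset correlation in which enough members were measured.

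These marker lists also differed within the control group. From the spread between libraries, the 95% interval of the shift was -0.0019 to 2.31 for the macrophage list, -0.09 to 2.33 for the stellate list, -0.81 to 2.79 for the lymphocyte list and 0.40 to 0.78 for the endothelial list. Relative to the control mean, the macrophage list stood at 0.02, 0.58 and -0.59 on the log2 scale in Control replicates 1, 2 and 3, and at 1.64, 0.86 and 0.97 in Gata4LKO replicates 1, 2 and 3. The lymphocyte list stood at 0.31, 0.91 and -1.22 in the controls and at 1.09, 1.16 and 0.72 in the others, so the groups overlapped. The stellate list stood at -0.26, 0.85 and -0.58 in the controls and between 1.09 and 1.16 in the libraries labelled Gata4LKO. The endothelial list varied less, from -0.06 to 0.11 in the controls and from 0.55 to 0.67 in the others. Of 20 matrix genes 3 rose, 10 adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.582 with an estimated correlation). The matrix list stood at -0.15, 0.48 and -0.33 in Control replicates 1, 2 and 3 and at 0.39, 1.07 and 0.58 in Gata4LKO replicates 1, 2 and 3, so the groups overlapped. It did not pass with the marker score as a covariate, at 0.19 (camera adjusted p = 0.104; 2.87e-08 to 0.104 over the alternatives with the preset correlation). The basement membrane collagens Col4a1 and Col4a2 rose by 1.36 and 1.32 and Col6a3 by 1.15, and Col14a1 had 1.43 without passing. Bile duct (cholangiocyte) markers did not rise with the others: their mean was -0.35 over 10 members (camera adjusted p = 0.187), with 0 past the test over all genes or the list alone. That list was called lower without Control replicate 1, at a mean of -0.47 (camera adjusted p = 0.0306), and without Gata4LKO replicate 3, at -0.46 (0.0473), and its adjusted p ranged from 0.0306 to 0.844 over the alternatives with the preset correlation. Erythroid genes did not pass (camera adjusted p = 0.852), with 1 of 7 lower adjusted over the list alone; their mean was 0.10 while the test pointed down, and without Control replicate 3 the list was called lower, at -0.36 (0.0407; 0.000443 to 0.996 over the alternatives with the preset correlation).

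**Figure D3:**
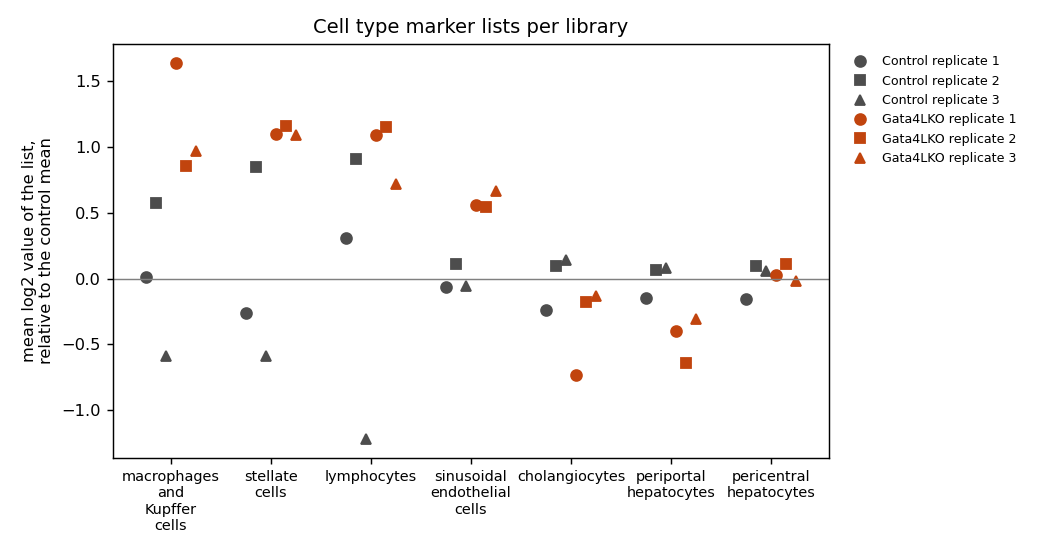
Mean log2 value of 7 cell type marker lists in each library, relative to the mean of the 3 controls (grey symbols for controls, orange for the libraries labelled Gata4LKO, shape for the replicate). Control replicate 3 stands lowest for macrophages, stellate cells and lymphocytes, and Control replicate 2 stands highest of the controls for these 3 lists.

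**Figure D4:**
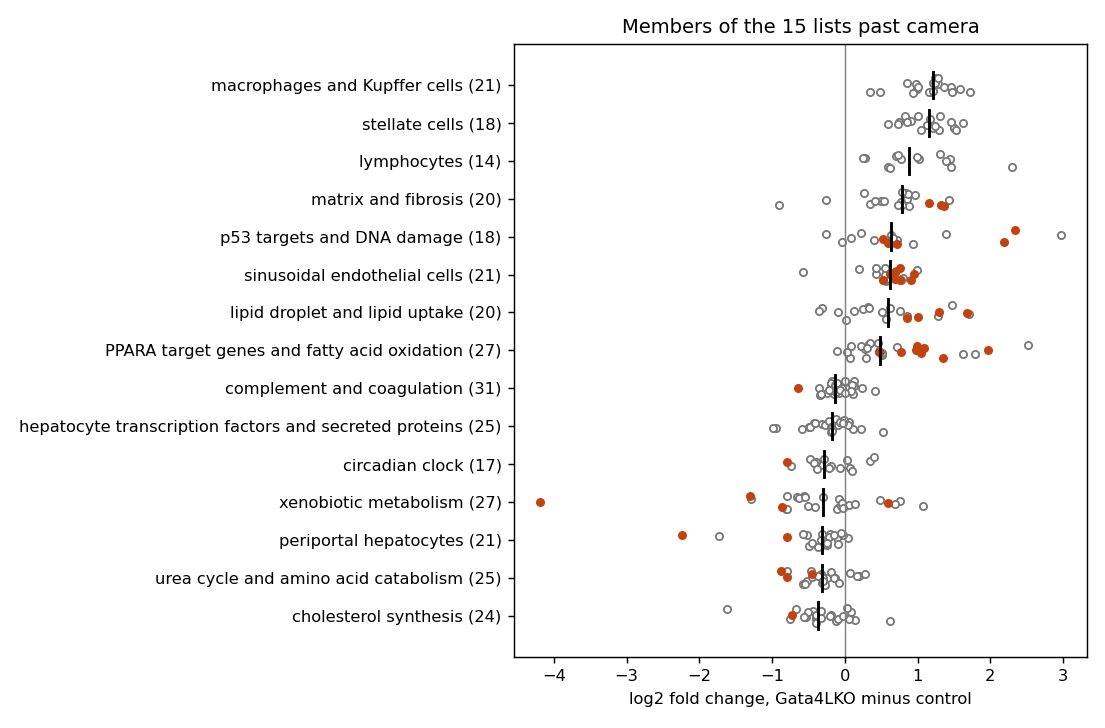
Log2 fold changes of the measured members of the 15 lists past camera, with the number of members in brackets. Filled points passed the limma test over all genes, open points did not, and the black line is the median, which lies between -0.36 and 1.21.

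The other lists did not pass camera. In the glucose list (camera adjusted p = 0.375) the glucokinase regulator Gckr fell by 0.52 and the glucose-6-phosphatase gene G6pc rose by 1.12, and Gys2 had -0.36 without passing, with 1 higher and 1 lower adjusted over the list alone. In the iron list (0.546) the hemojuvelin gene Hjv rose by 0.68, while Hamp, which encodes hepcidin, Trf and Smad6 had -0.94, -0.31 and 0.38, with 1 higher and 2 lower adjusted over the list alone. In the stress response list (0.655) Atf4 fell by 0.46, while Chac1, Creld2 and Trib3 had -1.44, 0.89 and -0.69, and 1 was lower adjusted over the list alone. In the interferon list (0.355) Oas2 rose by 1.25, while Oasl2, Gbp2 and Oasl1 had 0.71, 1.04 and 1.24, and 1 was higher adjusted over the list alone. That list was called higher without Gata4LKO replicate 3, at a mean of 0.36 (camera adjusted p = 0.0245; 0.0245 to 0.794 over the alternatives with the preset correlation). No member passed over all genes in the lists of acute phase genes (0.546), male-biased genes (0.655), female-biased genes (0.546), the growth hormone axis (0.603), immediate early genes (0.658) or mitochondrially encoded genes (0.64). Adjusted over the list alone, these 6 lists held 0, 1, 0, 0, 1 and 0 higher and 0, 1, 0, 2, 2 and 0 lower members. The growth hormone list had a mean of 0.05 and a median of -0.06 with the test pointing down, and the acute phase list a mean of -0.09 and a median of 0.04. Both means changed sign over the alternatives, ranging from -0.20 to 0.16 for the growth hormone list and from -0.42 to 0.09 for the acute phase list. Of the lists with too few measured members for camera, the 3 fetal genes, 3 neutrophil genes and 2 exocrine pancreas genes held none past the test over all genes, and 1, 2 and 0 higher adjusted over the list alone. The 3 adipose genes held 1, Cfd, and 2 adjusted over the list alone. Of the 33 lists tested, 15 passed camera, 8 higher and 7 lower, and 0 held with an estimated correlation. Some lists share members, such as Gls2 and Hal in the periportal and urea cycle lists, so the 15 are not all separate results. Camera with the preset correlation also passed 7 to 13 lists when the libraries were split in ways that mix the labels. Its calls alone therefore do not set the labelled groups apart. By fry, which tests whether a list moves on balance in 1 direction, 4 passed: the PPARA, hepatocyte, endothelial and p53 lists.

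The authors' deposited table of the same comparison listed 1367 genes with an adjusted p under 0.05, 868 higher and 499 lower. All 296 genes called by limma were among them with the same sign. In the authors' deposited table Gata4 had a log2 fold change of 0.47 (SE 0.13, adjusted p = 0.00809) and Apoa1 had -0.59 (SE 0.11, adjusted p = 1.53e-05). Abca1, Lcat, Scarb1 and Apob had adjusted p of 0.727, 0.951, 0.824 and 0.182 in the authors' deposited table.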

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

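The covariate was chosen after seeing the data, and the other settings beforehand. All 296 changed genes kept their sign under every setting in which they had a value. The number changed rose to 458 with equal library sums, 841 with library weights and 1370 with DESeq2. It fell to 25 without the variance trend and to 6 with the marker score, and ranged from 27 to 792 when single libraries were left out. At least 2-fold changes numbered 201, 350, 459, 25 and 6 under those 5 settings, and 24 to 478 without single libraries. Other settings gave 271 to 335 genes. Gata4 passed at 0.52 with equal sums, 0.48 with library weights and 0.47 with DESeq2, with adjusted p from 0.00712 to 0.478 over all settings. Camera called 11 to 17 lists under the other settings, 0 with an estimated correlation and 4 by fry. Of 626 list values, 19 lost a call and 1 called list, lymphocytes, turned its direction. The hepatocyte (camera adjusted p = 0.125), complement (0.186), xenobiotic (0.106) and clock (0.0933) lists lost theirs with quantile normalisation, at means of -0.15, -0.07, -0.37 and -0.22 against -0.21, -0.10, -0.38 and -0.22. The xenobiotic list also lost its call with a mean of at least 50, at a mean of -0.25 (0.0734). Complement lost its call with library weights, at -0.07 (0.093), and lymphocytes with DESeq2, at 0.71 (0.0646). With the marker score, cholesterol synthesis (0.721), matrix (0.104), xenobiotic (0.127), urea cycle (0.199), macrophage (0.0775) and stellate (0.156) lists lost theirs and the lymphocyte list turned to -0.46 (0.156). The first 6 had means of -0.04, 0.19, -0.37, -0.14, 0.28 and 0.19, against -0.32, 0.68, -0.38, -0.31, 1.16 and 1.12 without the score, so the xenobiotic mean hardly moved. The macrophage, stellate and lymphocyte lists are those the score is built from. In the same setting erythroid (0.000443), acute phase (0.00633) and immediate early genes (1.6e-05) were called lower. At an adjusted p under 0.01 the authors' deposited table held 743 genes. With the marker score, Abca1 (-0.12), Scarb1 (-0.034), Lcat (-0.11), Gata2 (-0.46) and Ptprc (-0.079) turned negative. Lcat ranged from -0.045 to 0.058 and Gata6 from -0.039 to 0.14 without single libraries, and Gata6 was -0.0012 with quantile normalisation and -0.0021 with library weights. None of these negative values passed the test. The cause of these shifts was not tested. With the marker score 5 of the 296 calls stayed: the median absolute log2 fold change went from 0.86 to 0.82 and the median standard error from 0.13 to 0.19, so calls ended mainly through lost precision, since the score differs between the groups. Genes under a mean of 10 were tested in the setting without a filter alone, which called 328 genes.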

Other observations

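The gene families, and the tests of the marker score, the label of Control replicate 2 by direction, the cell type lists, the library left out of the cell type lists, p53 and Cre, were chosen after the values were seen, and these tests, except that of Cre, had their bounds or markers reset after first values had been seen. The Serpina3 cluster on chromosome 12 held several genes that fell. Of 9 tested members, 4 fell (limma, Benjamini-Hochberg adjusted p under 0.05): besides Serpina3c, these were Serpina3f, Serpina3m and the pseudogene Serpina3l-ps, with log2 fold changes of -1.73, -1.18 and -4.53. The fold of Serpina3l-ps depends on the pseudocount, since its mean was 0.68 normalised reads in the libraries labelled Gata4LKO. Serpina3g, Serpina3k and Serpina3n had log2 fold changes of 1.21, 0.45 and 0.38 without passing. The annotated span of Serpina3m contains those of Serpina3k and Serpina3l-ps on the same strand, so their reads cannot be assigned with certainty. The Slc39 family of zinc importers also held changes of both signs: Slc39a4 and Slc39a2 fell, Slc39a5 rose by 2.21 (SE 0.34) from a mean of 7.34 normalised reads, and the other 10 of 13 tested members did not pass. The sterol acyltransferase gene Soat2 fell by 1.47 (SE 0.11, limma adjusted p = 0.0034) and Fabp2, a fatty acid binding protein gene, had a log2 fold change of -1.56 (SE 0.22, limma adjusted p = 0.021). These genes were chosen after their values were seen.

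A search over 422 sets of genes sharing a symbol root was also chosen after seeing the data. Genes of such a set need not be related. It gave 10 sets that passed camera with a preset correlation, all higher in the libraries labelled Gata4LKO. The Cd, Bmp, Adamts, Paqr, Chst, Rgs and Gdf sets were among them, with medians from 0.39 to 0.94, as were 11 toll-like receptor genes with a median log2 fold change of 1.24 (Benjamini-Hochberg adjusted p = 0.0018), 8 Ms4a genes at 1.23 (0.011) and 8 Gimap genes at 0.62 (0.023). Some of their members, such as Cd3e, Cd4 and Rgs5, also belong to the marker lists above, so these sets partly repeat those lists. None held with an estimated correlation (adjusted p = 0.97 for each). The macrophage and lymphocyte marker lists had medians of 1.21 and 0.88, and whether these sets follow them library by library was not tested.

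With the real groups 296 genes changed, against at most 1 in the 9 other splits of the 6 libraries into 3 and 3. For changes of at least 2-fold it was 119 against at most 1, and for lists past camera 15 against at most 13. In each case only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Between 7 and 13 lists passed camera in the other splits.

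Gata4 counts above those of all controls in the libraries labelled Gata4LKO were weighed first. With the label of any 1 library exchanged, the log2 fold change of Gata4 stayed positive, from 0.21 to 0.48. A single wrong label would therefore not turn it into a fall. If 1 library carried a wrong label, it could lie nearer the other group in most genes called from the other 5 libraries, with 50% set as the limit beforehand. Control replicate 2 lay nearer its own group's mean in 48.5% of 792 such genes, past that limit, and in 6 of the 20 with the smallest p, while the other libraries ranged from 74.1% to 89.3% and from 14 to 19 of 20. A wrong label would place it nearer the other group in both directions, yet this held for the higher genes alone (39.2% of 595 nearer its own group), and 76.6% of the 197 lower genes lay nearer its own, Serpina3c at 4965 and Dsg1c at 981 among them, which argues against a wrong label. Gata4 of endothelial or stellate cells is a candidate source that sorting hepatocytes would remove. Their listed markers of highest mean in the controls, Ptprb and Dcn, had means of 1745 and 2472 there and 2610 and 4741 in the others. With the marker score in the model Gata4 had 0.33 (95% interval -0.033 to 0.70), which decides nothing. Transcripts that keep exons outside the deleted part stay open because exons were not counted apart.

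The second pattern was the higher level of macrophage, stellate, endothelial and lymphocyte markers as lists, with per-library intervals above 0 for the endothelial list alone. Control replicate 3 is not the whole cause of the endothelial shift. On that list it stood at -0.05, between Control replicates 1 and 2 at -0.06 and 0.11. Leaving it out therefore could not remove the shift, which was 0.564 without it (95% interval 0.31 to 0.82). For the other 3 lists together the shift without that library was 0.689 (-0.30 to 1.68), the lymphocyte list having 0.38, so a control with few such cells stays open. A lower share of hepatocytes stays open too: the 4 lists moved 0.897 more than the 5 bile duct markers with a mean of at least 50 (-0.28 to 2.07), and 1.31 more (0.019 to 2.6) than all 10, some of which lie near the floor. More of these cells, more RNA per cell or differences in sampled tissue remain open, as does the genotype the labels name.

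Targets of p53 were the third pattern. Their mean log2 fold change with the marker score in the model was 0.70 (95% interval 0.053 to 1.36 from the spread between libraries). This argues, narrowly, against the share of macrophages, stellate cells and lymphocytes, as that score measures it, as the whole cause. The endothelial list kept a mean of 0.50 with that score (camera adjusted p = 1.05e-07 with the preset correlation). The score may therefore miss part of the other cells, and a share that it misses stays open. The list passed camera in that model with the preset correlation (adjusted p = 9.8e-06) but not with an estimated one (adjusted p = 0.708 with an estimated correlation). The higher level, a mean of 0.85, may stem from Cre or from the deletion the labels name, which the Gata4 counts did not show, and these cannot be told apart because no library had Cre without floxed Gata4. A control vector expressing Cre was not analysed here.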
